A study of Mus musculus with 2 samples.

How the data were processed

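RNA of mouse bone marrow-derived dendritic cells from 2 cultures was measured on oligonucleotide arrays, with 1 array for the control culture and 1 array for the culture that received conditioned medium. Total RNA was extracted with Trizol and biotin-labelled cRNA was prepared by the standard Affymetrix procedure, per the labels' protocols. The submitters' processing notes name Affymetrix Expression Console. Its version, the summarisation and normalization algorithm, and the genome build behind the probe sets are not given in the sources used here.

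The authors deposited 1 table with a value per probe set and array, taken here as log2 intensity because the values ran from -0.26 to 13.42 on the control array and from 0.02 to 13.50 on the conditioned-medium array, with medians of 4.10 and 4.09. The sorted values of the 2 arrays differed by a mean of 0.015 and by at most 0.28 on the log2 scale, so the 2 distributions were nearly the same. A shift of most genes in one direction would not be seen in such values. Background correction and the log base were not stated, and the base is an inference from the range. Of the 41345 probe sets, 1722 (4.16%) held exactly the same value on both arrays, with a median level of 3.15 among them.

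Gene names came from the array's platform annotation: 23521 probe sets (56.9%) had 1 gene symbol, 1814 had several and were not named, and 16010 were not in that annotation. The 23521 probe sets stood for 22180 genes, of which 21994 had their gene identifier, with the identical symbol, in a RefSeq gene table of assembly GRCm38.p6. Because no build is stated for the deposited values, no coordinates are given.

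Each gene was represented by the probe set with the highest mean of the 2 arrays. Genes were kept when the higher of their 2 values was at or above 4.10, the median of all values of both arrays, which kept 13712 genes (61.8%). The log2 difference was the value with conditioned medium minus the control value, and a fold is 2 raised to that difference. With 1 array per culture condition no test was possible, so no p-value, standard error or call of a changed gene is given. Genes were counted by a fixed rule of size, a difference of at least 2-fold.

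A total of 33 gene lists (782 entries, of which 705 were measured and 650 kept) were fixed before the data were examined, as were the size rule, the filter and the alternatives. For each list with at least 5 kept members, the median log2 difference was placed among the medians of 10000 random lists of the same size drawn from kept genes in the same 20 bins of mean level. Such a percentile describes these 2 arrays and is not a p-value, since genes of a list can move together in any pair of cultures. The genes named were, by a rule also fixed before, the 12 with the largest and the 12 with the smallest difference (leaving out provisional names and genes with another detected probe set of opposite sign), from each list the 2 highest and 2 lowest kept members, and 10 genes named whatever their values: Ifnb1, Cxcl10, Il6, Tnf, Il12b, Il1b, Cd40, Cd80, Cd86 and Sting1. Ccr7, Relb, Cd83, Fscn1, Rsad2, Fosl2, Trp53inp1, Ifih1, Ddx58, Ifi204, Btg2 and Sesn2 were named in addition, after their values were seen. Where the lower of a gene's 2 values lay under 4.10, its fold was also computed against 4.10, since a value that low may be background. No detection calls were used.

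Technical spread was read from genes with 2 or more probe sets above the filter: their log2 differences had a pooled SD within genes of 0.46 (787 degrees of freedom). This covers differences between probe sets on the same 2 arrays and not the spread between cultures or animals. Precision is limited by the number of arrays.

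The alternatives were quantile normalization, subtraction of a loess curve of the difference on the level (lowess with a fraction of 0.3 and 3 iterations), centring of the arrays on kept genes, the mean of all probe sets of a gene, no filter, a filter at the 75th percentile, a filter on the mean of both arrays, all pairs of probe sets of a gene for their agreement, and thresholds of 1.5-fold and 3-fold. The counting and the list percentiles were tested on simulated data with 13712 genes, a noise SD of 0.3 and 200 genes moved: 94.0% of genes moved by 1.5 on the log2 scale and 100.0% of those moved by 3 were counted, 12 unmoved genes passed 2-fold, and 39 of 40 unmoved lists of 25 genes fell inside the middle 95% of random lists. That noise is lower than the pooled SD between probe sets, so the simulation was repeated with an SD of 0.46: 83.0% and 100.0% of the moved genes were counted, 391 unmoved genes passed 2-fold, and again 39 of 40 unmoved lists fell inside. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.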

Results

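Gene expression was measured in mouse dendritic cells grown from bone marrow, which the submitters call GMDC. One culture was the control and the other received medium conditioned by E0771 cells, a mouse mammary tumour line, that had been treated with topotecan, an inhibitor of topoisomerase I. The comparison addressed how gene expression in the dendritic cells differs when they are cultured with such medium. Each condition was represented by 1 array, so no value below has a replicate error, and every difference is between 2 arrays. The labels do not say what medium the control received, so an effect of the topotecan treatment of the tumour cells cannot be separated from an effect of tumour-conditioned medium as such. Across all 41345 probe sets the arrays correlated with Pearson's r = 0.93 and Spearman's rho = 0.92; probe sets are not independent replicates.

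Interferon beta and a broad set of interferon-inducible and inflammatory genes were higher in the cells given conditioned medium, while neutrophil marker genes and proliferation genes were lower. Of 13712 kept genes, 1184 (8.63%) were at least 2-fold higher and 938 (6.84%) were at least 2-fold lower. The larger differences were more often upward, with 155 genes at least 8-fold higher and 36 at least 8-fold lower. Ifnb1, which encodes interferon beta, had the largest difference of all kept genes as deposited: its log2 intensity (probe set 17427064) was 2.19 in the control and 10.73 with conditioned medium, a ratio of 372. The control value lay in the lower range of the array, and measured against the filter level of 4.10 the ratio was 99.0. Il6, the gene of interleukin-6, was 169-fold higher (4.11 and 11.51). Its control value lay only just above the filter level and may be background too. Against that level Il6 came before Ifnb1, as did Fxyd4 (108-fold).

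The other 10 of the 12 genes named for the highest differences were 2 chemokines of interferon-activated cells, Cxcl11 (86.4-fold) and Cxcl10 (69.5-fold), the interferon-inducible Ifi205 (62.1-fold), the Ifit family relative Ifit1bl1 (88.9-fold), the apolipoprotein L family gene Apol9b (82.2-fold), the activation marker Cd69 (73.0-fold), the ion transport regulator Fxyd4 (116-fold), the G-protein-coupled receptor gene Gpr33 (75.1-fold), the vanin Vnn3 (73.3-fold) and Hamp (70.7-fold), which encodes the iron-regulating hormone hepcidin. Fxyd4, Ifit1bl1, Apol9b, Gpr33, Vnn3 and Hamp lay under the filter level in the control, and against that level they were 108, 67.5, 59.7, 14.7, 49.2 and 23.4-fold higher, in this order. The 12 genes named for the lowest differences included 4 genes of myeloid granules: Camp, the cathelicidin gene (46.5-fold lower), Ngp (35.9-fold), Ctsg, the gene of cathepsin G (17.5-fold), and Elane, that of neutrophil elastase (17.0-fold). The stefin genes Stfa1 (32.2-fold) and Stfa2l1 (22.8-fold), the lectin gene Clec4b1 (35.6-fold), the mitotic cyclin gene Ccnb2 (25.2-fold), Tmem273 (22.0-fold), Cbr2 (17.3-fold), Shcbp1 (16.6-fold) and the immunoglobulin segment Igh-VS107 (15.4-fold, with a log2 difference of -1.76 over the mean of its probe sets) completed them. With conditioned medium Camp, Elane, Clec4b1, Shcbp1, Igh-VS107 and Cbr2 lay under the filter level. Against it the first 5 of these were 22.1, 10.1, 9.19, 9.79 and 7.26-fold lower, in this order, and Cbr2 had a log2 difference of -3.70. The order of the lowest genes thus rests in part on signal that may be background. Against the filter level Ngp, Stfa1, Ccnb2 and Stfa2l1 came before Camp. Stefin, Ifi200, Ifit, Schlafen, guanylate-binding protein, interferon alpha, H2 and apolipoprotein L genes belong to families of similar sequence, and their probe sets could share signal between members.

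**Figure D1:**
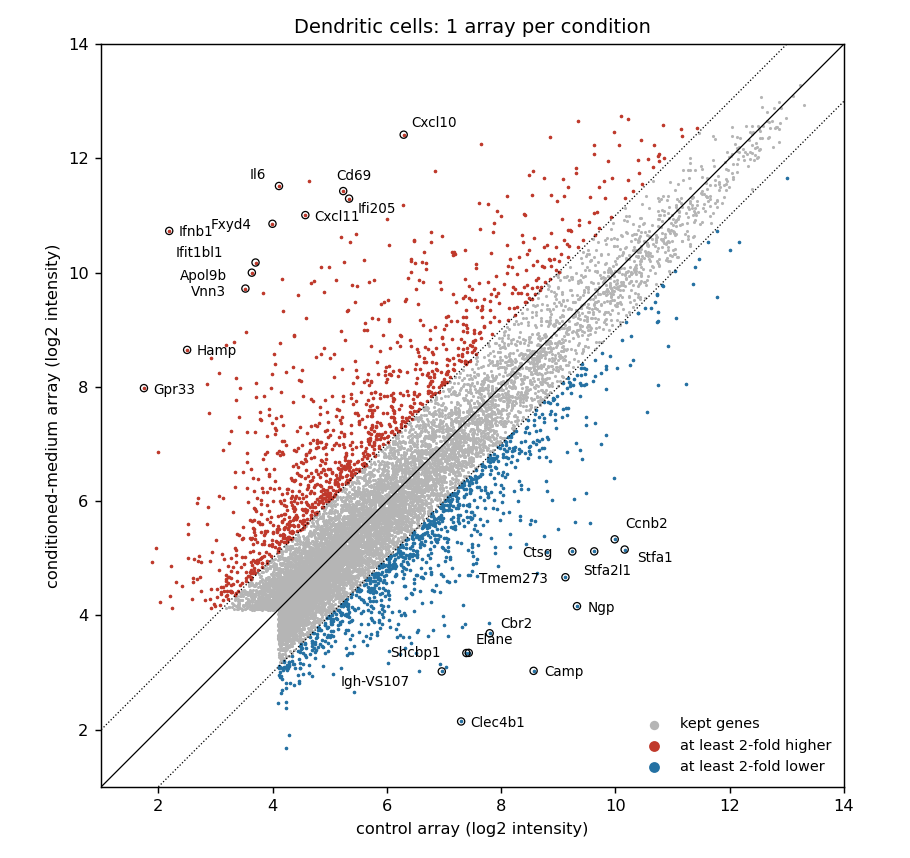
Log2 intensity of each of the 13712 kept genes (points) on the control array (x axis) and on the conditioned-medium array (y axis), with the line of equality, dotted lines at 2-fold, 1184 genes at least 2-fold higher in red and 938 at least 2-fold lower in blue. The 12 highest and 12 lowest differences under the naming rule are circled and named; Ifnb1 lies farthest from the line, at 2.19 and 10.73.

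Interferon-stimulated genes, which include antiviral effectors and sensors, were higher as a group. Of the 45 kept members, 37 were at least 2-fold higher, 0 were 2-fold lower and 8 lay between, and all 45 differences were above 0. Ifi205 (62.1-fold) and Slfn4 (43.0-fold, 29.0-fold against the filter level) led the list as deposited. Against that level Slfn4 had a log2 difference of 4.86 and came after Rsad2 (5.24). Ifitm3 (12.38 in the control and 12.57 with conditioned medium) and Parp14 (log2 difference 0.43) differed least. The median log2 difference was 2.07 (quartiles 1.21 and 2.62), above every one of 10000 random lists of genes at the same levels, whose highest median was 0.56. The interferon-gamma-inducible GTPases and class I presentation genes had a similar median of 2.08, with 18 of 22 kept members at least 2-fold higher and 0 lower. Socs1, a feedback inhibitor of cytokine signalling, was 16.4-fold and the guanylate-binding protein gene Gbp3 16.1-fold higher, whereas Ciita (log2 difference 0.08) had nearly equal values on both arrays. B2m differed by 0.06, but at 13.22 and 13.29 it lay close to the highest values of the arrays, where saturation could hide a difference. Ifitm3 also lay high enough for this to be possible.

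Among the interferon genes themselves, 7 of 15 measured were kept and 2 of these were at least 2-fold higher: Ifnb1 and Ifnk (4.98-fold, and 2.34-fold against the filter level). The interferon alpha gene Ifna4 (log2 difference -0.11) and the interferon lambda gene Ifnl3 (0.02) were nearly level. The list's median of 0.61 lay at percentile 98.4 of random lists, but at 91.6 when the 8 members under the filter level were included. In the list of nucleic acid sensing and STING pathway genes, 7 of 22 kept members were at least 2-fold higher, 0 were lower and 15 lay between, with a median of 0.45 (percentile 99.8). Its members Zbp1, Ifih1, Ddx58 and Ifi204 also stand in the interferon-stimulated list. The percentile is therefore not separate evidence of a rise in sensing genes as such. Tlr3, a receptor for double-stranded RNA, was 6.27-fold (4.91-fold against the filter level) and Zbp1, a nucleic acid sensor, 5.03-fold higher. Sting1, which encodes the adaptor STING, was 1.98-fold higher (8.97 and 9.95), and Irf8 and Ddx41 had log2 differences of -0.88 and -0.68.

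Inflammatory cytokines, chemokines and costimulatory genes were also higher. Of 33 kept cytokine and NF-kB target genes, 22 were at least 2-fold higher, 0 lower and 11 between, with a median log2 difference of 1.82. After Il6, the largest member was Acod1, which makes itaconate (34.5-fold); Il1b was 8.88-fold and Tnf 6.46-fold higher. Il12b, a subunit of interleukin-12, was low on both arrays (4.31 and 5.15, 1.80-fold), and Cd14 (-0.14) and Marco (-0.20) were nearly level. Of 23 chemokines, 15 were at least 2-fold higher and 3 lower, with a median of 1.40. Ccl17 (3.52-fold lower, 2.96-fold against the filter level) and Ccl22 (3.35-fold lower, 2.45-fold against it), 2 ligands of the receptor CCR4, were the lowest. Of 24 kept genes of dendritic cell maturation and costimulation, 15 were at least 2-fold higher, 7 lay between and 2, again Ccl17 and Ccl22, were lower. Cd40 (17.1-fold), Cd86 (17.0-fold) and Cd80 (9.07-fold), which encode costimulatory surface proteins, were on the higher side, and the list's median was 1.47. The 7 between included Ccr7 (log2 difference -0.31), Relb (-0.17), Cd83 (0.20) and Fscn1 (0.40), so the list did not rise throughout. The medians of these 3 lists lay above all 10000 random lists each.

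**Figure D2:**
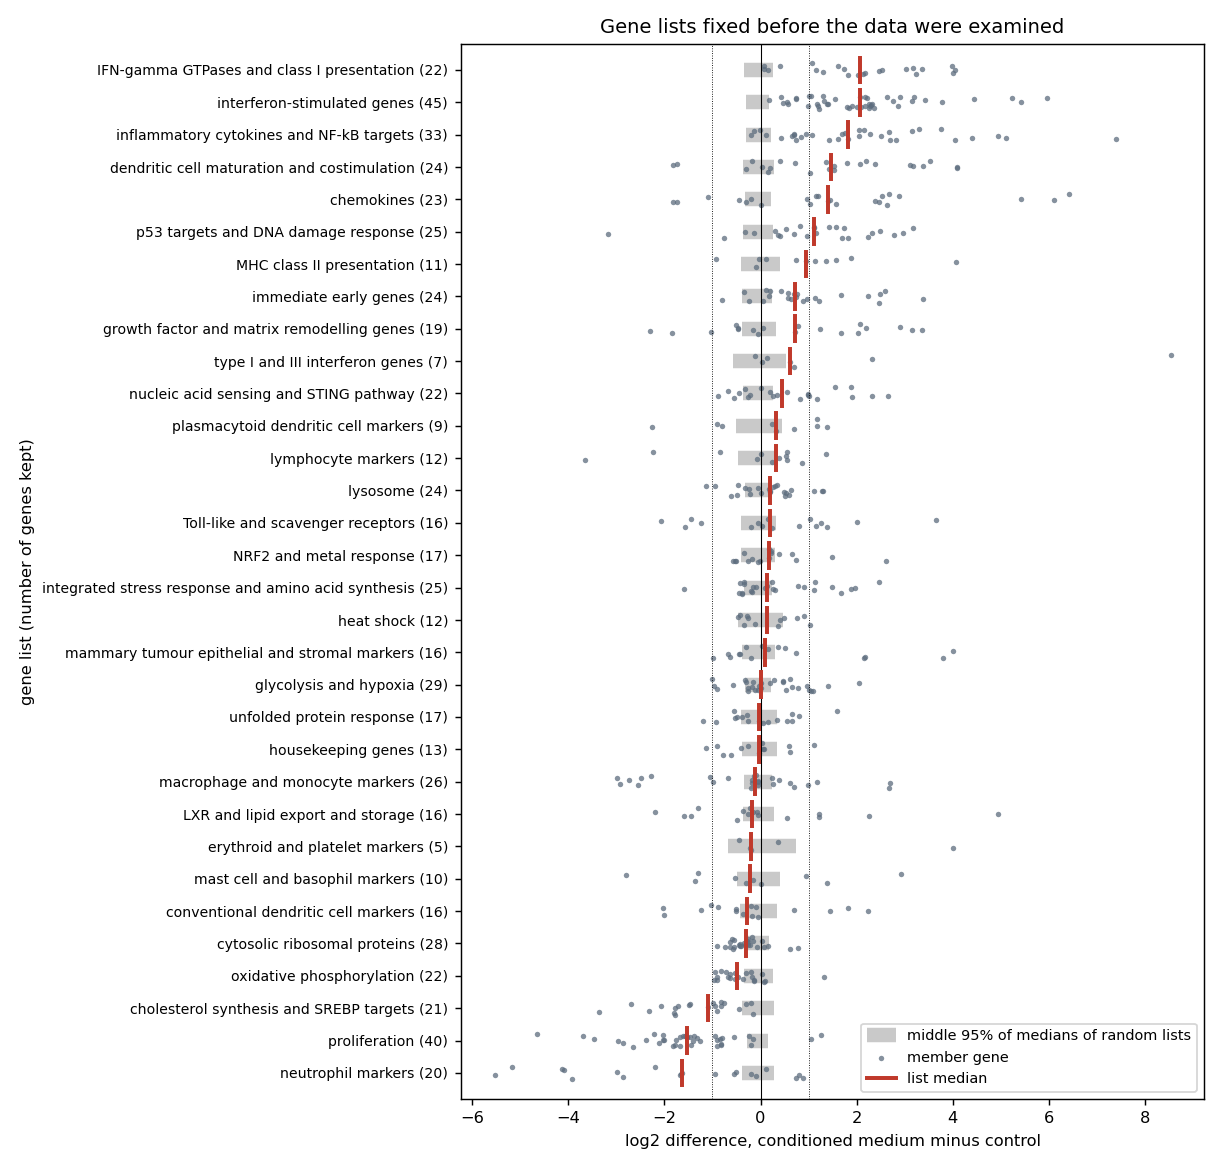
Log2 difference, conditioned medium minus control (x axis), of each kept member (points) of the 32 gene lists with at least 5 kept members (y axis, number kept in parentheses), with the list median (red bar), the middle 95% of medians of 10000 level-matched random lists (grey band) and dotted lines at 2-fold. The medians of 12 lists lie at or above the upper end of the band and those of 5 at or below its lower end, where 1.6 lists in all would lie by chance if lists were random; the interferon-gamma-inducible and interferon-stimulated lists are highest, at 2.08 and 2.07, and neutrophil markers lowest, at -1.64.

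MHC class II presentation genes were moderately higher: 5 of 11 kept members were at least 2-fold higher, 0 lower and 6 between, with a median of 0.96 (percentile 99.9). H2-Oa, a subunit of the peptide-loading modulator H2-O, was 16.9-fold and H2-Aa, a classical class II chain, 3.68-fold higher, while Lgmn had a log2 difference of -0.92 and H2-DMb2 of -0.10. Among 24 kept immediate early genes, 8 were at least 2-fold higher and 0 lower (median 0.72, above all random lists). Klf4 (10.5-fold) and Ier3 (6.07-fold) were the highest, and Egr3 (-0.80) and Egr2 (-0.34) the lowest as deposited. Against the filter level Egr3 differed by -0.17, and Egr2 and Fosl2 (-0.25) were then the lowest. Toll-like and scavenger receptors were mixed, with 6 of 16 at least 2-fold higher and 4 lower (median 0.20, percentile 92.3). Tlr5, the flagellin receptor, was 12.7-fold higher (10.1-fold against the filter level) and Timd4 4.04-fold higher (2.93-fold against it), and the lipoprotein receptor gene Scarb1 was 4.23-fold and Stab1 2.99-fold lower.

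Proliferation genes were lower and p53 target genes higher. Of 40 kept proliferation genes, 27 were at least 2-fold lower, 11 lay between and 2 were at least 2-fold higher, with a median of -1.52, below all random lists. The mitotic genes Ccnb2 (25.2-fold lower) and Ube2c (12.9-fold lower) were lowest, and Ccne1 (2.40-fold) and Tpx2 (2.06-fold) were the 2 higher members. Neutrophil markers were lower on the same array, with a median of -1.64. Of 25 kept p53 and DNA damage response genes, 14 were at least 2-fold higher, 10 between and 1 lower, with a median of 1.11, above all random lists. The highest members as deposited were Cd80, which also stands in the maturation list, and Perp (7.76-fold, 6.74-fold against the filter level). Against that level Perp had a log2 difference of 2.75, next to 2.77 for Trp53inp1, so their order is uncertain. The lowest were Sesn1 (9.03-fold lower, 5.32-fold against the filter level) and Ckap2 (-0.76).

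Genes of cholesterol synthesis were lower as a group: 11 of 21 kept members were at least 2-fold lower, 10 between and 0 higher, and all 21 differences were below 0. Sqle, the gene of squalene epoxidase, was 10.3-fold lower (8.76 and 5.39) and Fdps, that of farnesyl diphosphate synthase, 6.50-fold lower, while Ebp (-0.19) and Insig1 (-0.15) were nearly level; the median of -1.09 lay below all random lists. In the list of lipid export and storage genes, 4 of 16 were at least 2-fold higher and 4 lower (median -0.19, percentile 25.5). Ch25h, which encodes the enzyme that makes an oxysterol from cholesterol, was 30.7-fold and Angptl4 4.75-fold higher, and Pparg, a regulator of lipid storage (4.58-fold), and Lpl, the lipoprotein lipase gene (3.04-fold), were lower. Oxidative phosphorylation genes had small, mostly downward differences: 18 of 22 were below 0 and 1, Cycs (2.51-fold higher, with 5 detected probe sets), passed 2-fold, with a median of -0.50 (percentile 0.08) and Ndufb8 (-0.97) and Ndufb5 (-0.94) the lowest.

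Most of the remaining metabolic and stress lists had medians within the middle 95% of random lists, and the lysosomal and ribosomal lists lay just outside it. Glycolysis and hypoxia genes had a median of 0.02 (percentile 77.1; 5 of 29 at least 2-fold higher, 1 lower), with Pfkfb3 4.11-fold (3.56-fold against the filter level) and Adm 2.63-fold higher. Integrated stress response genes had a median of 0.13 (percentile 90.2; 7 of 25 higher, 1 lower), led by Nupr1 (5.54-fold) and Slc3a2 (3.89-fold), with Pck2 lower (log2 difference -1.58). Unfolded protein response genes (median -0.02, percentile 61.6) held 1 higher gene, Ppp1r15a (3.03-fold), and 1 lower gene, Herpud1 (2.30-fold). Heat shock genes (0.13, percentile 79.9) held 1 higher gene of 12, Hspa1a (2.04-fold), and the NRF2 and metal response genes (0.18, percentile 91.2) 2 of 17, Mt2 (6.13-fold) and Slc7a11 (2.80-fold). Lysosomal genes had a median of 0.20 (percentile 98.0; 3 of 24 higher, 1 lower), with Neu1 2.47-fold and Gla 2.43-fold higher. Cytosolic ribosomal protein genes had a median of -0.30 (percentile 2.36) and 0 of 28 past 2-fold in either direction. These 2 lists came inside that range under some alternatives, at percentiles 95.8 (mean of all probe sets) and 9.06 (quantile normalization). Housekeeping genes had a median of -0.03 (percentile 61.6), with Actb 2.17-fold higher and Hprt 2.19-fold lower among 13.

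Markers of cell types did not differ in one direction. Neutrophil markers were lower: 11 of 20 were at least 2-fold lower, 9 lay between and 0 were higher, with a median of -1.64, below all random lists, from Camp and Ngp at the low end to Cebpe (0.80) and Csf3r (0.89). Macrophage and monocyte markers had a median of -0.12 (percentile 43.1), with 7 of 26 at least 2-fold lower and 3 higher. Chil3, a chitinase-like secreted protein, was 7.92-fold and Csf1r, the receptor for the macrophage growth factor CSF1, 7.61-fold lower, whereas Arg1 (6.47-fold) and Ly6c1 (log2 difference 2.68, 4.37-fold against the filter level) were higher. Conventional dendritic cell markers had a median of -0.29 (percentile 12.6), with Batf3 (4.08-fold) and Clec10a (4.03-fold) lower, and Dpp4 (4.75-fold) and Irf4 (3.55-fold) higher. Mammary tumour epithelial and stromal markers were a check for tumour material carried with the medium. Of 26 measured, 16 were kept, and without a filter the median over all 26 was 0.02 (percentile 76.5). Of the 16 kept, 12 lay between, 4 were at least 2-fold higher and 0 lower, with a median of 0.10 (percentile 83.1). Dcn (16.1-fold, 14.7-fold against the filter level) and Cdh1, the gene of E-cadherin (13.8-fold), were the highest, and Acta2 (-0.99) and Col3a1 (-0.68) the lowest. Cdh1 had a second detected probe set, and the mean over its probe sets gave a log2 difference of 2.17 instead of 3.79.

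**Figure D3:**
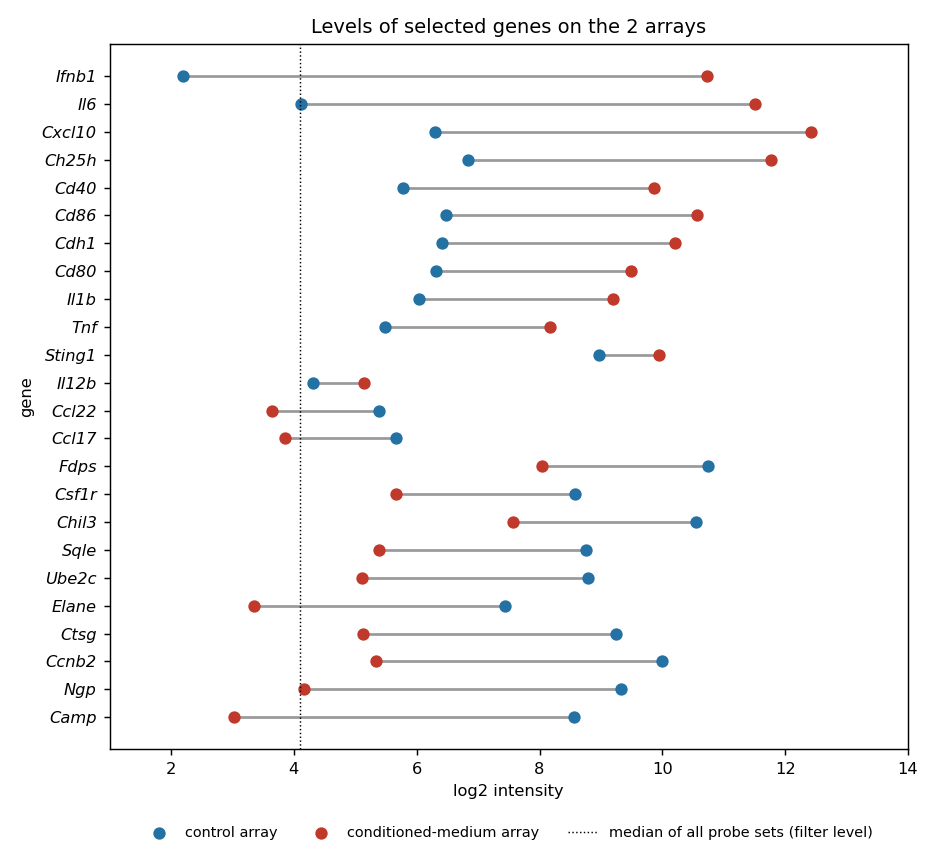
Log2 intensity (x axis) of 24 genes (y axis) on the control array (blue) and the conditioned-medium array (red), 1 array each and so without error bars, with a dotted line at the filter level of 4.10. Ifnb1 runs from 2.19 to 10.73, Sting1 from 8.97 to 9.95, and Camp from 8.57 down to 3.03, under the filter level.

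The error of these differences could be judged from probe sets of the same gene only. Of 92 genes that were at least 2-fold apart and had a second detected probe set, 83 (90.2%, exact 95% interval 82.2 to 95.4%) had a second difference of the same sign, against 472 of 652 (72.4%) of all genes with 2 or more detected probe sets; in 38 of the 92 the second probe set also passed 2-fold in that direction. In simulated arrays with noise of the size measured between such probe sets (SD 0.46), 391 unmoved genes passed 2-fold, both directions together. Here 1184 genes were counted as higher and 938 as lower. The simulated noise holds no variation between cultures, RNA preparations or arrays. The 391 is therefore not an estimate of how many counted genes would differ between 2 cultures of one condition. The interval covers counting error and not the spread between cultures, for which there was 1 array per condition.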

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

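The results here were singled out because signal lay in probe sets that no comparison used. Of the probe sets absent from the platform annotation, 823 of 7026 at or above the filter level (11.7%) were at least 2-fold higher with conditioned medium than on the control array, and 664 (9.45%) were at least 2-fold lower. Among them, probe set 17414796 was highest, with 3.72 in the control and 10.14 with conditioned medium, and probe set 17538820 was lowest, with 5.81 and 0.17. In each pair the lower value lay under the filter level of 4.10, where signal is not told from background, so these ranks and the sizes of the differences are uncertain. Of the probe sets with several gene symbols, 90 of 1278 (7.04%) were at least 2-fold higher and 69 (5.40%) lower. No gene is named for either class.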

How the results depend on the processing

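With 1 array per condition, no replicate could be left out and no paired analysis was possible because each group holds a single sample. The 2 counts of genes moved by more than 1.5 times only with the fold threshold: at 1.5-fold, 2274 genes were higher and 2458 lower, and at 3-fold, 568 and 290, so that the majority was downward at the lowest threshold and upward at the others. Under the other alternatives 1004 to 1308 genes were higher and 752 to 1096 lower. The median of the interferon-stimulated genes ranged from 2.03 to 2.18. Over all pairs of probe sets of a gene, undetected ones included, agreement was counted where the first by mean level was at least 2-fold apart. The same sign was found in 178 of 228 such pairs (78.1%), against 90.2% for second detected probe sets under the main rule. The cause of the drop was not tested. Of 221 alternative values of list medians, 218 moved by less than the pooled SD between probe sets of 0.46, 3 moved by more and 0 changed sign in a list outside the middle 95% of random lists; the 3 came with the filter at the 75th percentile, which took p53 targets to 1.64, cholesterol synthesis to -1.60 and growth factors to 1.24. Of the 17 lists outside the middle 95%, 14 stayed outside under all alternatives, and the interferon gene, lysosomal and ribosomal lists did not; conventional dendritic cell markers left it in 1 alternative, at percentile 2.35 with the mean of probe sets. Of 620 alternative values of named genes, 616 moved by less than 0.46; the other 4 came with the mean of all probe sets, for Cdh1 (2.17), Ch25h (4.47), Ighm (-1.35) and Igh-VS107 (-1.76). The alternative by probe set suffix was not run, since the IDs are plain numbers, nor those on a pseudocount, since the values are on a log scale. Of the genes 2-fold higher, 258 had a control value under the filter level, and of those 2-fold lower, 226 had such a value with conditioned medium; their folds rest on signal that may be background.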

Other observations

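Genes of growth factors and matrix remodelling were higher as a group: 8 of 19 kept members were at least 2-fold higher, 3 lower and 8 between, with a median log2 difference of 0.71, above all 10000 random lists. Hbegf, the gene of an epidermal growth factor receptor ligand, was 10.3-fold and the collagenase gene Mmp13 8.94-fold higher, and Tgfb1 (4.91-fold) and Igf1 (3.58-fold) were lower. Markers of other cell types in bone marrow cultures went both ways. Mast cell and basophil markers (median -0.23, percentile 25.7) had Cpa3 (log2 difference -2.81, 5.36-fold against the filter level) and Prss34 (2.56-fold) lower, and the histidine decarboxylase gene Hdc 7.63-fold higher (3.88-fold against the filter level). Lymphocyte markers (0.31, percentile 95.4) had Ighm 12.6-fold (log2 difference -3.65, and -1.35 with the mean of its probe sets) and Cd79b 4.72-fold lower and Gzmb 2.57-fold higher (1.39-fold against the filter level). Plasmacytoid dendritic cell markers (0.31, percentile 93.7) had Lair1 4.80-fold lower and the interferon-inducible Bst2 2.59-fold and Ly6c2 2.27-fold higher. Of 5 kept erythroid and platelet markers (-0.19, percentile 37.6), 1 passed 2-fold, the carbonic anhydrase gene Car2 (16.1-fold higher). Of the sex-specific transcripts 1 was kept, Xist, with 6.96 in the control and 6.11 with conditioned medium.

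The tests on signal level and on later neutrophil stages were chosen after the result was seen, as were the division of neutrophil genes into precursor granule and later-stage genes, the requirement on 5 single later-stage genes and the bootstrap interval of the progenitor median. The lists of progenitor genes and of further p53 targets were written after the fixed lists had been examined and before their own values were. A bias tied to signal level alone would let random lists at the same levels reach the median of the interferon-stimulated genes, but the highest of 10000 was 0.56 against 2.07. These are the same random lists that gave the percentile of that list, so the comparison adds no further evidence. Whether the pattern belongs to the condition stays open, since there were 0 further arrays on which a chance or batch difference between the 2 cultures or arrays could be tested. The conditioned medium, the biological difference that the design names, is untested in the same sense.

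A candidate explanation for the lower neutrophil granule genes is a lower share of neutrophil-lineage cells in the culture. A loss of all stages alike would lower early and late genes together, but the median of 10 later-stage genes lay 3.0 above that of 8 precursor granule genes on the log2 scale (-0.54 and -3.54). This gap alone met the bound first set against that explanation; because S100a8, S100a9 and other later genes are also made by other myeloid cells, 5 less shared ones were then required to stand apart too, and 4 did while Retnlg (7.79 and 3.86; named after its values were seen) did not. Fewer granulocyte and monocyte progenitors would lower other progenitor genes; the 12 kept genes of such a list had a median of -0.082 (percentile 51.2), above the -0.25 set beforehand as the bound against it, but 6 were higher and 6 lower, from Ms4a3 (6.71-fold lower) to Serpinb1a (2.79-fold higher), and the bootstrap 95% interval over genes, -0.56 to 0.47, spans that bound. A loss of cells and lower expression in the same cells cannot be told apart here. The gap met the criterion first set, but it cannot exclude an equal loss of every stage. Signal of the shared later genes from other myeloid cells could keep their median up.

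The higher p53 targets raise the hypothesis of a p53 response that also takes in targets outside the fixed list. Of the fixed list, Cd80, Btg2 and Sesn2 also stand in the maturation, immediate early and integrated stress response lists, respectively. Their higher values therefore do not point to p53 alone. A second list of p53 targets had a median of 0.34 over 17 kept genes (percentile 97.4), short of the 0.5 set beforehand as its sign and above the 0.25 set as its absence. Psrc1 was 3.78-fold and Apaf1 2.39-fold higher, and Triap1 2.34-fold lower. The test leaves the hypothesis open, and whether topotecan itself reached the dendritic cells with the medium stays open too.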
